A study of Homo sapiens with 6 samples.

How the data were processed

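RNA of MCF7 cells was measured on 6 Affymetrix Human Genome arrays of the U133 Plus series, 1 for each combination of 3 siRNA states and 2 estrogen states, from biotin-labelled cRNA made from total RNA, per the labels' protocols. The deposited values are intensity summaries per probe set on a linear scale, with array medians of 181 to 216 and values up to 184086. RMA, which normalizes between arrays, is named in the submitters' processing notes with no version. The scale, its ceiling and any offset are not given in the sources used here and stay unknown, and the values reach above the range of a common array scanner. The logarithm to base 2 was taken here with nothing added. Scanner files and detection calls were not used here. The number of arrays limits the precision.

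The table holds 54675 probe sets, of which 62 are array controls. The platform annotation names 1 gene for 41091 of them, several for 1801 and none for 11721; probe sets with several genes or none were not named. Of those with 1 gene, 41043 matched a current gene by its identifier, which gave 19775 genes. A gene's value was that of its probe set with the highest mean over the 6 arrays, and 8972 of the tested genes had more than 1 probe set. Genes whose mean lay under the 40th percentile of all probe sets (intensity 96.77) were not tested, which left 14168.

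Groups were taken from the sample titles. The main comparisons used limma 3.58.1 in R 4.3.3 on all 6 arrays, with siRNA state and estrogen as additive terms, which leaves 2 residual degrees of freedom, the default empirical Bayes moderation, and Benjamini-Hochberg adjustment at 0.05. Adjusted p-values of genes come from limma's gene-wise test, and those of lists from camera over all list tests unless fry is named. Counts adjusted over the list alone are corrected over that list's members in 1 contrast, not over lists or contrasts. Members of a list share the same 6 arrays, so such counts are not counts of independent findings. Contrasts were estrogen, TFAP2C siRNA against none, TFAP2A siRNA against none, and TFAP2C against TFAP2A siRNA. To ask whether the estrogen response of 1 siRNA state differed from the others, a term for estrogen in that state was added, which leaves 1 residual degree of freedom. That fit treats the responses of the remaining states as alike and assumes that the lone pair of arrays varies as they do.

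Gene lists, contrasts, filters, the named genes and the alternatives were fixed before the data were examined. There were 17 lists with 415 genes in all, of which 376 were on the array and 349 were tested: estrogen-induced, estrogen-repressed, DNA replication and G1/S, mitosis and G2/M, luminal epithelial, basal and mesenchymal, AP-2 family and cofactors, genes linked to AP-2 in breast cells, growth factor receptors and ligands, immediate early, interferon response, p53 target, sterol synthesis, unfolded protein response, hypoxia and glycolysis, cytosolic ribosomal protein, and markers of other cell types. The lists come from general knowledge of these pathways, and some genes stand in several. Each list was tested with limma's camera at a preset correlation of 0.01, and with Benjamini-Hochberg adjustment over all 119 tests of lists and contrasts. Medians were set beside 10000 random lists matched on mean level. The named genes were, per comparison, up to 12 that rose and 12 that fell by size among those past the threshold with the same direction in every pair of arrays. Where fewer than 10 passed, the 10 of smallest p were taken and said not to have passed. From each list came up to 4 members each way past the threshold, or 2 by size where none passed, and 18 genes were always looked at. After the main counts were seen, the same rule was applied to the calls of the trend fit. Not all genes that the rule allows are printed.

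Other settings fixed beforehand were no filter, a filter at the 60th percentile, the mean of a gene's probe sets, every probe set by itself, leaving out probe sets whose names mark shared sequence, subtracting array medians, quantile normalization, empirical Bayes with a mean-variance trend and robust moderation, a threshold of 0.1, dropping the other term of the model, and leaving out each array in turn. For the lists they were a correlation estimated from the arrays and fry. Adding 64 before taking log2, and every planned setting together with the trend fit, were added after seeing the data. A covariance and an overlap of calls between the siRNA effects were set beside values from 100 and 20 simulations of unchanged groups that share their controls.

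The tests were checked on simulated data for the 14168 genes, in 5 runs with 200 changed genes each. The noise was normal, with the spreads that the trend fit gave for these arrays, so the simulations assume that fit's variance model. Their rates need not be those of the real calls. For the estrogen contrast the default fit recovered 0%, 0%, 48% and 79.6% of genes changed by 0.5, 1, 2 and 4 on the log2 scale, with 3.6% of calls false, and the trend fit 34%, 67.6%, 83.6% and 88%, with 8.1% false. For TFAP2C siRNA the default fit recovered 0%, 0%, 14% and 74% with 3.5% false, and the trend fit 24.4%, 62.4%, 80.4% and 90% with 8.7% false. For the response under TFAP2C siRNA the default fit recovered 0% at each size, and the trend fit 4.4%, 42.4%, 72.4% and 85.2% with 20.7% false. The trend fit thus exceeded the nominal 5% in these simulations.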

Results

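MCF7 is a breast cancer cell line that carries the estrogen receptor and grows in response to estrogen. TFAP2C and TFAP2A encode AP-2 gamma and AP-2 alpha, related transcription factors of the AP-2 family. RNA was measured on 6 oligonucleotide arrays, 1 for each combination of 3 siRNA states (TFAP2C siRNA, TFAP2A siRNA and no siRNA) and 2 estrogen states. The series title names the question, which estrogen pathways TFAP2C controls. No combination had a replicate array, so the number of arrays limits the precision: the estrogen effect averages over 3 pairs of arrays and each siRNA effect over 2. The labels do not say that the arrays came from separate cultures, so the p-values of genes measure the spread between these arrays, which may be technical. With 1 array per combination, that spread also holds any dependence of the estrogen effect on siRNA state. A gene whose estrogen response differs between the states thus gets a larger SE. The p-values of lists from camera at the preset correlation measure the spread between genes, not between arrays. A siRNA without a target in the cells was not among the states analysed here. The labels do not say whether the cells without siRNA were mock transfected, so differences from them can include any effect of transfection. Median intensities of the arrays lay between 181 and 216, and log2 values correlated between arrays at Pearson's r of 0.926 to 0.965 over the 14168 genes tested. The ACTB control probe sets differed by 0.69 on the log2 scale between the 3' and 5' ends on the array with neither siRNA nor estrogen, against 0.26 to 0.54 on the others. Tests are limma with its default moderation (the default fit) and, beside it, limma with a mean-variance trend and robust moderation (the trend fit), which was fixed beforehand as another setting and called far more genes. In simulated data 3.6% of the default fit's calls for estrogen were false, and 8.1% of the trend fit's.

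Each siRNA was followed by a lower level of its own target. The log2 intensity of TFAP2C was 11.48 without and 11.88 with estrogen under TFAP2C siRNA, against 13.65 and 13.64 without siRNA and 13.49 and 14.10 under TFAP2A siRNA. TFAP2A stood at 10.22 and 10.26 under TFAP2A siRNA, against 11.74 and 11.47 without siRNA and 12.53 and 12.37 under TFAP2C siRNA. Against no siRNA, TFAP2C differed by -1.96 (SE 0.20), which leaves 25.6% of its level, and TFAP2A by -1.36 (SE 0.14), which leaves 38.9%, or by -0.53 with the mean of its probe sets. These differences passed with the trend fit (adjusted p = 1.76e-05 and 0.000456) and not with the default fit (adjusted p = 0.0707 and 0.131). TFAP2A rose by 0.85 under TFAP2C siRNA with the trend fit (adjusted p = 0.00361, against 0.0992 with the default fit), while TFAP2C differed by 0.15 under TFAP2A siRNA (adjusted p = 0.59 with the trend fit). A second TFAP2C probe set differed by -1.13 under TFAP2C siRNA. Of the other TFAP2A probe sets under TFAP2A siRNA, the brighter differed by -1.41 and the dimmer by 1.18. The dimmer probe set stood at log2 levels of 3.38 to 6.34, below the intensity filter on every array. It is part of the mean that gave -0.53. TFAP2B, another family member, was not tested because its mean lay below the intensity filter, with log2 levels of 3.27 to 7.24 on single arrays.

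**Figure D1:**
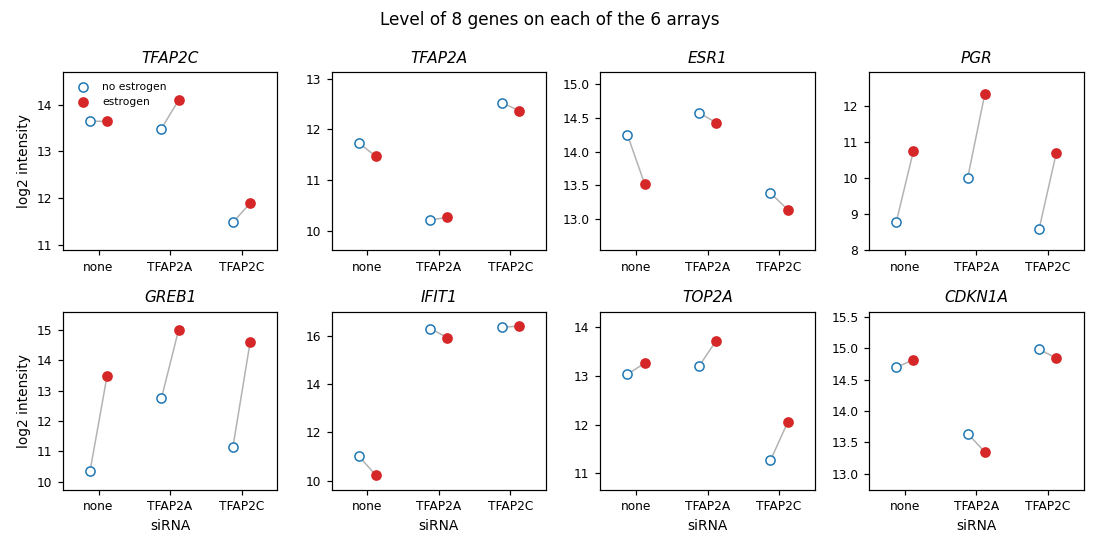
Log2 intensity of 8 genes on each of the 6 arrays, by siRNA state, with open circles for no estrogen, filled circles for estrogen and a line joining each pair. TFAP2C stands at 11.48 and 11.88 under its own siRNA and TFAP2A at 10.22 and 10.26 under its own, IFIT1 lies above 15 under both siRNAs, and TOP2A is lowest under TFAP2C siRNA.

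Estrogen went with higher levels of its known target genes in all 3 siRNA states. Of 50 tested estrogen-induced genes 47 were higher with estrogen, by a median of 0.70 (camera adjusted p = 2.25e-24; adjusted p = 0.799 with an estimated correlation), and 27 rose with the trend fit. GREB1, an estrogen receptor cofactor, rose by 2.94 (SE 0.28), PGR, the progesterone receptor, by 2.14 (SE 0.12), and MYBL1, a Myb family transcription factor, by 1.94 (SE 0.16), all with the trend fit and in each of 3 pairs of arrays. With the default fit no member passed over all genes (31 had an unadjusted p under 0.05), and 26 passed adjusted over the list alone. Estrogen-repressed genes had a median of -0.44, with 15 of 19 lower (adjusted p = 1.32e-05; adjusted p = 0.821 with an estimated correlation). Of these IL1R1, the interleukin-1 receptor, fell by 1.70 and CCNG2, an atypical cyclin of resting cells, by 0.66 with the trend fit, while KLF4 rose by 0.53. With the default fit 9 repressed genes passed adjusted over the list alone.

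Genes of the cell cycle stood higher with estrogen. The medians were 0.45 for replication and G1/S genes, with 32 of 33 higher (adjusted p = 6.84e-14; adjusted p = 0.919 with an estimated correlation), and 0.39 for mitosis and G2/M genes, with 30 of 31 higher (adjusted p = 1.16e-12; adjusted p = 0.799 with an estimated correlation). With the trend fit 6 replication genes rose, among them CDC45, a helicase component, by 0.83 and MCM7 by 0.70, and 3 mitosis genes, among them UBE2C, a ubiquitin-conjugating enzyme of mitotic exit, by 0.71. Limma's default fit passed 0 genes of either list, over all genes or adjusted over the list alone (17 and 11 at an unadjusted p under 0.05). Immediate early genes, many of them transcription factors, answer growth signals within minutes. They had a median of 0.15, or 0.0827 with array medians subtracted, with 10 of 16 higher (camera adjusted p = 0.0376, and 0.831 with an estimated correlation). Of these genes 5 rose with the trend fit, among them EGR3 by 1.72, FOS by 1.02 and MYC by 0.96. The default fit passed 4 immediate early genes adjusted over the list alone. All 31 ribosomal protein genes were higher, by a median of 0.08 (adjusted p = 0.0166; adjusted p = 0.919 with an estimated correlation), and that call was lost when array medians were subtracted (adjusted p = 0.181) or quantiles were equalised (adjusted p = 0.671).

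Other genes that rose with the trend fit included CDH26, a cadherin (2.95, or 1.44 with the mean of its probe sets), PLAC1 (2.85), RBM24, an RNA-binding protein (2.73), and IGFBP4, a binding protein of insulin-like growth factors (1.64). CRY2, a repressor of the circadian clock, fell by 3.05, and this size and that of PLAC1 rest on levels below the intensity filter (CRY2 at log2 levels of 5.69, 6.43 and 5.31 with estrogen, PLAC1 at 5.72 and 5.99 on the arrays without estrogen that had no siRNA or TFAP2C siRNA). SCNN1A, a subunit of the epithelial sodium channel, fell by 1.64, though by only 0.03 with the mean of its probe sets, and IGFBP3 by 1.37. CXCL10, an interferon-induced chemokine, rose by 1.44, TFF1, a secreted trefoil peptide, by 0.57 and RERG by 0.79. Among genes chosen in advance that passed neither fit, CXCL12, a chemokine, differed by 1.26 (SE 0.47) and FREM2, TFAP2C, RET, GATA3, CCND1, CDKN1A, TFAP2A, EGFR, ERBB2, FOXA1 and ESR1 by 0.43 down to -0.37. In limma's default fit 0 of 14168 genes passed, with 1377 at an unadjusted p under 0.05 and a smallest adjusted p of 0.431. The 10 genes of smallest p, none of which passed it, were PGR, LINC00482, TMPRSS3, AIRE, BSND, CXCL10, ARHGAP36, FGF6, RAB3IL1 and GPR15LG. LINC00482 and AIRE lay below the filter on every array without estrogen, BSND on every array with it, and GPR15LG on 1 array. The trend fit called 236 (152 higher, 84 lower). Without the arrays lacking siRNA it called 470 (no estrogen left out) and 448 (estrogen left out), and without the TFAP2A siRNA arrays 119 and 115. With array medians subtracted it called 125 higher and 197 lower.

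TFAP2C siRNA was followed by a rise of interferon response genes. All 29 tested members were higher than without siRNA, by a median of 4.52 (adjusted p = 1.01e-31; adjusted p = 0.799 with an estimated correlation), 22 rose with the default fit over all genes, and all 29 passed adjusted over the list alone. OAS2, an enzyme of the antiviral RNase L pathway, rose by 6.36 (SE 0.25), IFIT3, which takes part in binding viral RNA, by 6.30 (SE 0.21), IFI27 by 6.24 (SE 0.18) and XAF1 by 6.18 (SE 0.18). PSMB8, a catalytic subunit of the immunoproteasome, rose by 9.03 (SE 0.19), a size that rests on log2 levels of 3.44 and 3.68 without siRNA, far below the filter, and HCP5 and APOL3 also lay below it without siRNA. The default fit also called HCP5, CMPK2, SAMD9, APOL3 and IFI44 higher. Those that fell were MKX, a homeobox transcription factor, by 3.70, SLC27A6, a fatty acid transporter, by 3.44, KMO, an enzyme of the kynurenine pathway, by 3.26, SLITRK6 by 3.12, and GPER1, a membrane receptor for estrogen, by 2.15, along with IL2RB, STON1, ATP2B2 and HMGCLL1. Under TFAP2C siRNA MKX stood at log2 levels of 6.57 and 6.09, below the filter, so its size rests on dim values, and IL2RB, ATP2B2 and 1 array of STON1 also lay below it.

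Cell cycle genes stood lower under TFAP2C siRNA. All 33 replication and G1/S genes were lower, by a median of -1.01 (adjusted p = 9.4e-13; adjusted p = 0.919 with an estimated correlation), and so were all 31 mitosis and G2/M genes, by a median of -1.03 (adjusted p = 2.74e-14; adjusted p = 0.799 with an estimated correlation). With the trend fit 27 replication and 29 mitosis genes fell, among them EXO1, an exonuclease, by 1.99, TYMS, thymidylate synthase, by 1.97, HMMR, a spindle protein, by 1.57 and TOP2A, topoisomerase II alpha, by 1.49. The default fit passed none of them over all genes (27 and 29 at an unadjusted p under 0.05), and 27 and 29 adjusted over the list alone.

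Other lists moved less under TFAP2C siRNA. Immediate early genes had a median of 0.65, with 14 of 16 higher (adjusted p = 2.19e-05; adjusted p = 0.799 with an estimated correlation), and 12 rose with the trend fit, among them NR4A1, an orphan nuclear receptor, by 2.92 from log2 levels of 6.17 and 7.91, of which the former lies below the filter, and FOS by 1.45. For p53 target genes the median was -0.34, with 16 of 22 lower (adjusted p = 0.00966; adjusted p = 0.799 with an estimated correlation), and SPATA18 and ZMAT3 fell by 1.76 and 1.24 with the trend fit while GDF15, a stress cytokine, rose by 0.88 (0.33 with the mean of its probe sets). Sterol synthesis genes had a median of -0.46, with 14 of 17 lower (adjusted p = 0.0282; adjusted p = 0.919 with an estimated correlation), and ACAT2 and IDI1, enzymes of the pathway, fell by 0.89 and 0.77 with the trend fit. Adjusted over the list alone the default fit passed 7 immediate early, 9 p53 and 2 sterol genes. Estrogen-induced genes went both ways, with 27 higher and 23 lower (adjusted p = 0.556): HSPB8, a small heat shock protein, rose by 2.92, and ELAPOR1 fell by 3.23, MYB fell by 2.46 (1.38 with the mean of its probe sets) and TFF3 fell by 2.42 with the trend fit. Adjusted over the list alone 7 of these passed the default fit. Estrogen-repressed genes had a median of -0.22 (adjusted p = 0.495) and ribosomal protein genes of -0.04 (adjusted p = 0.495).

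Among genes chosen in advance, FREM2, an extracellular matrix protein, fell by 2.11 under TFAP2C siRNA, RET, a receptor tyrosine kinase, by 1.71, RERG by 0.64 and ESR1, the estrogen receptor, by 0.62, while GREB1 rose by 0.94 and MYC by 0.76, all with the trend fit. The ESR1 value comes from its brightest probe set, and the mean of the gene's probe sets gave 0.02. That mean includes the dimmest probe set, which differed by 2.61 at a mean log2 level of 5.24, below the filter. The remaining ESR1 probe sets differed by -1.04 to 0.77. PGR, TFF1, CCND1, ERBB2, EGFR, CDKN1A, CXCL12, FOXA1 and GATA3 passed neither fit, with differences of -0.39 to 0.27. The -0.39 is that of CXCL12, whose second probe set, nearly as bright, differed by -1.58. In all, the default fit called 66 genes (57 higher, 9 lower) and the trend fit 2593 (1104 higher, 1489 lower), which hold 65 of the 66. With any array left out the default fit called 0, with 1 residual degree of freedom, and the trend fit called 1587 without the TFAP2C siRNA array lacking estrogen. With array medians subtracted the trend fit called 870 higher and 1889 lower.

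TFAP2A siRNA was also followed by a rise of interferon response genes. All 29 were higher than without siRNA, by a median of 3.98 (adjusted p = 2.06e-39; adjusted p = 0.799 with an estimated correlation), 13 rose with the default fit over all genes and all 29 passed adjusted over the list alone. OAS2 rose by 5.93 (SE 0.25), IFI27 by 5.89 (SE 0.18), XAF1 by 5.75 (SE 0.18) and IFIT3 by 5.58 (SE 0.21), and BST2, which tethers budding virus to the cell, by 4.35 (SE 0.16). PSMB8 rose by 8.30 from the same low levels. CCDC9B was the 1 gene that fell with the default fit, by 2.87 (SE 0.12), to log2 levels of 5.31 and 4.60, below the filter.

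All 22 p53 target genes stood lower under TFAP2A siRNA, by a median of -0.75 (adjusted p = 1.08e-09; adjusted p = 0.799 with an estimated correlation). With the trend fit 16 fell, among them SPATA18 by 1.82, ZMAT3 by 1.33, CDKN1A, the cyclin-dependent kinase inhibitor p21, by 1.26, and FAS, a death receptor, by 1.22. The default fit passed none of them over all genes (17 at an unadjusted p under 0.05) and 16 adjusted over the list alone. Of 50 estrogen-induced genes 37 were higher, by a median of 0.46 (adjusted p = 1.36e-05; adjusted p = 0.799 with an estimated correlation). AGR3 rose by 2.03, GREB1 by 1.95, CALCR by 1.89 and PGR by 1.42 with the trend fit, whereas TFF3, ELAPOR1 and RET fell by 1.82, 1.65 and 0.88. Estrogen-repressed genes had a median of -0.57, with 17 of 19 lower (adjusted p = 0.00121; adjusted p = 0.919 with an estimated correlation), and PSCA and PIK3IP1 fell by 2.13 and 1.27 while TXNIP rose by 1.02 with the trend fit. Adjusted over the list alone 12 induced and 9 repressed genes passed the default fit.

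Cell cycle genes stood slightly higher under TFAP2A siRNA. Replication and G1/S genes had a median of 0.37, with 32 of 33 higher (adjusted p = 1.36e-07; adjusted p = 0.919 with an estimated correlation), and mitosis and G2/M genes of 0.20, or 0.34 with array medians subtracted, with 26 of 31 higher (adjusted p = 0.00121; adjusted p = 0.919 with an estimated correlation). E2F8, a repressor among the E2F factors, rose by 1.07 and MKI67, a marker of proliferating cells, by 0.84 with the trend fit. Limma's default fit passed 0 genes of either list, over all genes or adjusted over the list alone (6 and 3 at an unadjusted p under 0.05). Ribosomal protein genes had a median of -0.16, with 30 of 31 lower (adjusted p = 0.0249; adjusted p = 0.919 with an estimated correlation), and that call was lost when array medians were subtracted (adjusted p = 0.38), quantiles were equalised (adjusted p = 0.536) or probe sets were averaged (adjusted p = 0.0603). Immediate early and sterol synthesis genes had medians of 0.12 and -0.18 (adjusted p = 0.117 and 0.332).

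Further genes that passed the trend fit under TFAP2A siRNA were GPNMB, a membrane glycoprotein, which fell by 2.56, IGFBP3, which fell by 2.00, DAB2, an endocytic adaptor, which fell by 3.25 to log2 levels of 6.87 and 5.26, of which the latter lies below the filter, and ESR1, which rose by 0.61. With the mean of a gene's probe sets DAB2 fell by 1.52 and ESR1 rose by 0.39. TFAP2C, TFF1, MYC, CCND1, FREM2, RERG, ERBB2, EGFR, CXCL12, FOXA1 and GATA3 passed neither fit, with differences of -0.57 to 0.66. The 0.66 is that of CXCL12, whose second probe set differed by -0.35. The default fit called 25 genes (24 higher, 1 lower) and the trend fit 1392 (583 higher, 809 lower), which hold all 25. With any array left out the default fit called 0, and the trend fit called 717 and 586 without the TFAP2A siRNA arrays lacking and receiving estrogen. With array medians subtracted, which moved the median difference of all genes from -0.07 to 0.06, the trend fit called 1132 higher and 523 lower.

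Set directly against each other, the siRNAs differed in the cell cycle lists. Under TFAP2C siRNA all 33 replication genes were lower than under TFAP2A siRNA, by a median of -1.43 (adjusted p = 2.58e-22; adjusted p = 0.831 with an estimated correlation), and all 31 mitosis genes, by a median of -1.27 (adjusted p = 5.45e-21; adjusted p = 0.799 with an estimated correlation). With the trend fit EXO1 was lower by -2.37, E2F8 by -2.07, TTK, a spindle checkpoint kinase, by -1.82 and TOP2A by -1.80. Adjusted over the list alone the default fit passed 32 replication and 29 mitosis genes. Immediate early genes had a median difference of 0.51, or 0.29 with array medians subtracted, with 13 of 16 higher under TFAP2C siRNA (adjusted p = 0.00966; adjusted p = 0.799 with an estimated correlation), among them ATF3 at 1.59 with the trend fit. For interferon response genes it was 0.43, or 0.22 with array medians subtracted, with 27 of 29 higher (adjusted p = 0.000258; adjusted p = 0.919 with an estimated correlation), against the 4.52 and 3.98 that separated the siRNAs from no siRNA.

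Estrogen-induced genes were lower under TFAP2C than under TFAP2A siRNA, by a median of -0.27, or -0.48 with array medians subtracted, with 33 of 50 lower (adjusted p = 0.00119; adjusted p = 0.799 with an estimated correlation), and repressed genes higher, by 0.32, or 0.11 with array medians subtracted, with 16 of 19 higher (adjusted p = 0.0249; adjusted p = 0.919 with an estimated correlation), a call lost with the mean of a gene's probe sets (adjusted p = 0.0981). AGR3 differed by -2.36, MYB by -2.51, PGR by -1.53, ESR1 by -1.23 and GREB1 by -1.01, all past the trend fit. These values come from each gene's brightest probe set, and the mean of its probe sets gave -0.76 for MYB, -0.37 for ESR1 and -0.64 for GREB1. The ESR1 mean again includes its probe set below the filter. The p53 target genes differed by a median of 0.23 with 17 of 22 higher (adjusted p = 0.031; adjusted p = 0.831 with an estimated correlation), or 0.02 with array medians subtracted, which ended that call (adjusted p = 0.0512). CDKN1A differed by 1.42 and GDF15 by 1.14, past the trend fit. Adjusted over the list alone the default fit passed 11 induced, 4 repressed, 2 p53 and 1 immediate early gene. Limma's default fit called 0 of 14168 genes between the siRNAs, with 3095 at an unadjusted p under 0.05 and a smallest adjusted p of 0.137. The 10 genes of smallest p, none of which passed, were CCDC9B, AGR3, ARID5A, CDC42EP2, FBXO5, NFKBIL1, SLC26A1, TFAP2A, CHST11 and TAT. Further genes, PGR and CDKN1A among them, shared that adjusted p. Under TFAP2A siRNA CCDC9B, ARID5A and SLC26A1 lay below the filter on both arrays, and NFKBIL1 and TAT on 1. The trend fit called 2136 (1042 higher, 1094 lower under TFAP2C siRNA), and 3328 and 3333 without the arrays of no siRNA lacking and receiving estrogen, 622 without the TFAP2A siRNA array with estrogen, and 1240 and 1363 without the TFAP2C siRNA arrays lacking and receiving it. Subtracting array medians moved the median difference of all genes from 0.07 to -0.14 and the trend fit's calls to 472 higher and 2288 lower.

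Both siRNA effects were measured against the same arrays without siRNA, which by itself makes them alike. Across genes, which are not independent replicates, they correlated at Pearson's r of 0.576, against 0.499 for simulated unchanged groups. Their covariance was 0.271 against a simulated 0.0902, while the share of genes with the same sign, 64.5%, lay below the simulated 66.7%. With the TFAP2C effect taken without and the TFAP2A effect with estrogen, so that no array was shared, r was 0.170, and 0.315 the other way round. The default fit called 24 genes higher under both siRNAs, where independent lists would share 0.0966, and the trend fit 331 higher and 405 lower under both, where they would share 45.4 and 85.0. Simulated unchanged groups that share their controls had a median of 0 shared calls in 20 simulations with the trend fit. No gene was changed in those simulations, so adjusted calls are rare there whether or not controls are shared. That count therefore cannot show how much overlap the shared arrays add where many genes are called. The trend fit called 52 genes in opposite directions. Part of these overlaps may come from the shared arrays.

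**Figure D2:**
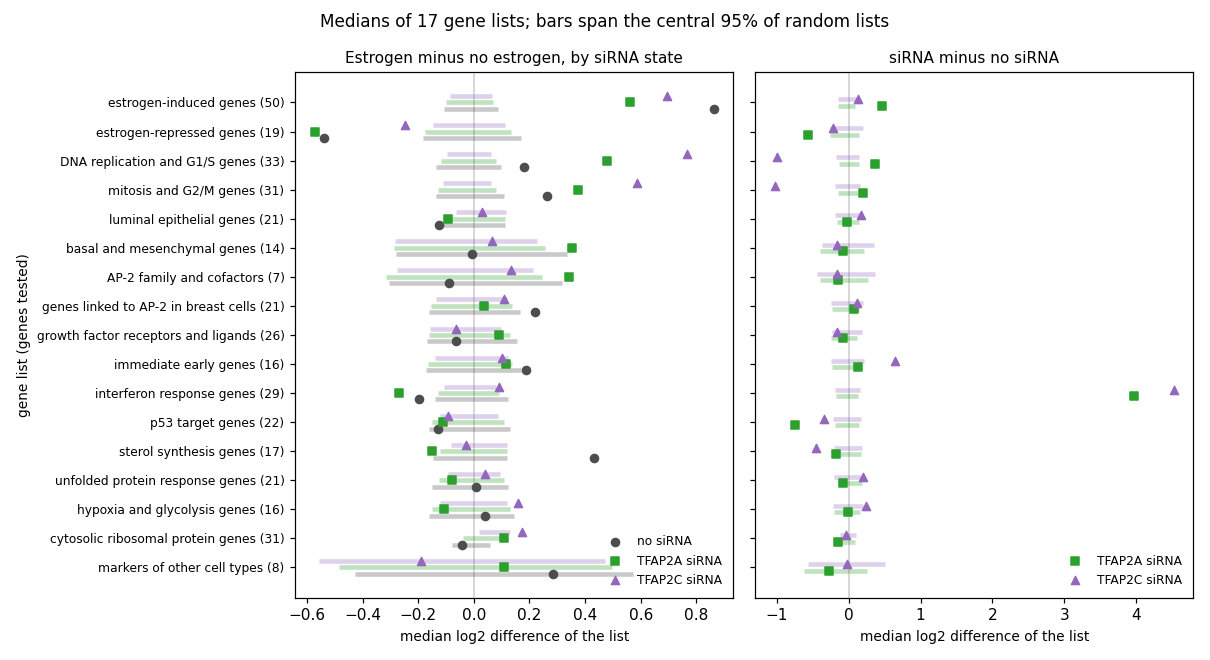
Median log2 difference of 17 gene lists, on the left with estrogen minus without in each siRNA state and on the right with each siRNA minus no siRNA, with bars for the central 95% of random lists matched on mean level. Estrogen-induced genes have medians of 0.86, 0.56 and 0.69 without siRNA, under TFAP2A siRNA and under TFAP2C siRNA, and interferon response genes stand at 4.52 and 3.98 under TFAP2C and TFAP2A siRNA.

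Whether the estrogen response depended on the siRNA state was read from 1 pair of arrays per state. Estrogen-induced genes had a median response of 0.86 without siRNA, 0.56 under TFAP2A siRNA and 0.69 under TFAP2C siRNA, each above the central 95% of random lists. By camera with the preset correlation, neither this list nor the estrogen-repressed list passed for a difference in response between states. At 2-fold or more, 809 genes were higher and 528 lower without siRNA, 670 and 627 under TFAP2A siRNA, and 716 and 726 under TFAP2C siRNA, which has no replicate check. Of the 809 genes higher without siRNA, 56.5% were higher with estrogen under TFAP2A siRNA and 55.4% under TFAP2C siRNA, and of the 151 above the 60th percentile of intensity 72.8% and 68.9%. Of the 528 lower without siRNA, 55.7% and 58.1% were lower, and 67.0% and 77.7% of the 94 above that percentile. Of those higher under TFAP2A or TFAP2C siRNA 63.7% and 60.6% were higher without siRNA, and above that percentile 78.9% of 114 and 78.9% of 123. Of those lower under TFAP2A or TFAP2C siRNA 49.4% each were lower without siRNA, and above that percentile 56.7% of 90 and 62.4% of 93. CXCL12 had responses of 2.28 without siRNA, 1.33 under TFAP2A siRNA and 0.17 under TFAP2C siRNA, and its second probe set 1.48, 1.81 and 0.29. Its response under TFAP2C siRNA differed from the others by -1.63 (SE 0.56) and passed neither fit (adjusted p = 0.861, and 0.103 with the trend fit). PGR responded by 1.98, 2.33 and 2.11, and GREB1 by 3.15, 2.25 and 3.43, in the same order of states.

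Some gene lists differed in their response between states by camera with the preset correlation, on 1 pair of arrays per state. Each state was set against the mean of the others, so calls of a list in different states share the same responses. Such calls are not independent findings. Each fit also treats the other states as alike, which a call of the same list in another state contradicts. Replication and G1/S genes responded less without siRNA than in the other states, by a median of -0.35 with 30 of 33 lower (adjusted p = 6.33e-05; adjusted p = 0.919 with an estimated correlation), and more under TFAP2C siRNA, by 0.37 with 29 higher (adjusted p = 2.74e-05; adjusted p = 0.919 with an estimated correlation). Sterol synthesis genes responded more without siRNA, by 0.60 with all 17 higher (adjusted p = 1.29e-05; adjusted p = 0.919 with an estimated correlation). Limma's default fit called 0 genes for each state, with 982 (no siRNA), 724 (TFAP2A siRNA) and 857 (TFAP2C siRNA) at an unadjusted p under 0.05. In simulated data for TFAP2C siRNA, the response simulated here, it recovered 0% of changed genes at every size tried, so the count for that state says nothing about how many responses differ. The trend fit called 0, 0 and 10. Of the 10, SLC25A42, GRIK5, SKA1 and IGFBP5 responded more under TFAP2C siRNA and MYLK-AS1, IL11RA, PRDM11, ACP4, SH3PXD2B and CLDN19 less. In data simulated with the trend fit's own spreads 20.7% of such calls were false, a rate that need not be that of these 10. All but IGFBP5 and CLDN19 of these lay below the intensity filter on at least 1 array. The genes of smallest p in the default fit, none of which passed, included A1BG-AS1 and KRTAP8-1 without siRNA, PCAT19 and PINX1-DT under TFAP2A siRNA, and GUCA2A and ZNF204P under TFAP2C siRNA. Each gene named in that sentence lay below the intensity filter on at least 1 array.

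The remaining lists passed in none of the 4 comparisons of estrogen and siRNA states. Luminal epithelial genes had a lowest adjusted p of 0.287 (estrogen), basal and mesenchymal genes of 0.258 (TFAP2C against TFAP2A siRNA), the AP-2 family and its cofactors of 0.298 (TFAP2A siRNA) and genes linked to AP-2 in breast cells of 0.243 (estrogen). Growth factor receptors and ligands reached 0.675 (TFAP2C siRNA), unfolded protein response genes 0.0633 (between the siRNAs), hypoxia and glycolysis genes 0.173 (TFAP2C siRNA), and markers of other cell types, such as immune, stromal and blood vessel cells, 0.473 (TFAP2A siRNA). Members of these lists that passed the trend fit under TFAP2C siRNA included SPDEF, a luminal transcription factor, which fell by 1.78, CLDN4, a tight junction protein, which rose by 1.42 (0.24 with the mean of its probe sets), CDH3, P-cadherin, which fell by 1.88, and FGFR2, which fell by 1.73. With estrogen CAV1, caveolin 1, rose by 1.18 with the trend fit. Of 119 list tests 36 passed with the preset correlation and none with an estimated correlation, where the lowest adjusted p was 0.799. That version of camera uses both the estimated correlation, which was -0.0379 to 0.873 for the lists that passed, and the 2 or 1 residual degrees of freedom of the arrays, and these were not separated.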

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

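The tests of response differences were planned, but the results printed here were chosen because they passed. Each value is the estrogen response of a list in 1 siRNA state minus that in the other states, as a median log2 difference. It was picked out because camera with a preset correlation passed it. None passed with an estimated correlation (adjusted p = 0.919 for each). Values of the same list in different states are computed from the same responses, so they are not independent findings.

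Replication and G1/S genes differed by -0.35 without siRNA and by 0.37 under TFAP2C siRNA, with median responses of 0.18 without siRNA, 0.48 under TFAP2A siRNA and 0.77 under TFAP2C siRNA. Mitosis and G2/M genes differed by -0.26 without siRNA (adjusted p = 0.042) and by 0.29 under TFAP2C siRNA (adjusted p = 0.0227), with median responses of 0.26, 0.37 and 0.59. The former call was lost with the mean of a gene's probe sets (adjusted p = 0.0787), with array medians subtracted (0.0658) and after quantile normalization (0.0714).

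Interferon response genes differed by -0.21 under TFAP2A siRNA (adjusted p = 0.0376) and by 0.30 under TFAP2C siRNA (adjusted p = 0.000832). The former call was lost with the mean of probe sets (adjusted p = 0.199), medians subtracted (0.0512) and quantile normalization (0.0702). Sterol synthesis genes differed by 0.60 without siRNA and by -0.40 under TFAP2A siRNA (adjusted p = 0.00509), with median responses of 0.43, -0.15 and -0.03 without siRNA, under TFAP2A siRNA and under TFAP2C siRNA. Hypoxia and glycolysis genes differed by -0.26 under TFAP2A siRNA (adjusted p = 0.0413), and cytosolic ribosomal protein genes by -0.18 without siRNA (adjusted p = 0.00184). The hypoxia call was lost with medians subtracted (adjusted p = 0.0619) and quantile normalization (0.0519), and the ribosomal call with the mean of probe sets (0.199) and quantile normalization (0.544). With single genes, limma with trend and robust moderation called 10 whose response differed under TFAP2C siRNA, among them IGFBP5, a binding protein of insulin-like growth factors, with responses of -1.01, 0.07 and 1.52 in the same order of states.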

How the results depend on the processing

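Adding 64 before log2 and combining the planned settings with the trend fit were chosen after seeing the data; the other settings were planned. Where a setting moved a value, the cause was not tested, except that leaving out an array leaves 1 residual degree of freedom, and none for the response differences, which were not tested that way. The default fit called 0 genes for estrogen under every setting except the trend fit (236). For TFAP2C siRNA its 66 genes became 0 without a filter, 1653 with the stricter filter, 0 with every probe set by itself, 22 without probe sets of shared sequence, 381 with the offset, 841 at the threshold of 0.1, 219 without the estrogen term and 2593 with the trend fit. For TFAP2A siRNA the 25 became 0, 548, 0, 0, 71, 74, 68 and 1392 under the same settings and 9 with the mean of probe sets. Between the siRNAs the 0 became 1104 with the stricter filter and 2136 with the trend fit. The response differences stayed at 0 apart from 10 under TFAP2C siRNA with the trend fit. Leaving out any array gave 0 for each of the 4 comparisons. The trend fit's 236 for estrogen became 95 without a filter, 32 with the mean of probe sets, 140 without probe sets of shared sequence, 434 at the threshold of 0.1 and 0 without the siRNA term, and ranged from 115 to 470 with an array left out. Its count for TFAP2C siRNA became 1226 with the mean of probe sets and 1438 without the estrogen term (1587 to 3107 with an array left out). For TFAP2A siRNA it became 470 with the mean, 863 without probe sets of shared sequence and 461 without the estrogen term (586 to 1745), and between the siRNAs 812, 1362 and 917 (622 to 3333). Genes at 2-fold or more with estrogen numbered, for no siRNA, TFAP2A siRNA and TFAP2C siRNA, 2980, 2856 and 2959 at 1.5-fold, 610, 629 and 735 at 3-fold, 4411, 4374 and 4495 without a filter, 245, 204 and 216 with the stricter filter, and 2903, 2713 and 3084 over every probe set; the offset gave 819 and 762 for the former pair. The median response of estrogen-induced genes stayed within its resampling interval in every setting run.

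The fall of TFAP2C under its own siRNA passed with the stricter filter (-1.96), the offset (-1.94) and the trend fit (-1.96), and ranged from -2.22 to -1.71 with an array left out. That of TFAP2A passed with the stricter filter (-1.36) and the trend fit (-1.36), was -0.53 with the mean of probe sets, and ranged from -1.49 to -1.23 with an array left out. The TFAP2A mean includes a probe set that lay below the filter on every array. Of the genes whose sign turned, none had passed either fit, except ESR1 under TFAP2C siRNA (0.0204 with the mean of probe sets). That ESR1 mean includes a probe set whose mean level lay below the filter and which differed by 2.61. With the mean, CCND1 and GATA3 stood at 0.0579 and -0.15 for estrogen, ERBB2 at -0.21 under TFAP2C siRNA and CCND1 at 0.0183 under TFAP2A siRNA. Without probe sets of shared sequence GATA3 stood at -0.34 for estrogen and EGFR at -0.0401 under TFAP2C siRNA. GATA3 for estrogen was -0.0565 with array medians subtracted and -0.0569 after quantile normalization. With medians subtracted, CCND1, FREM2, EGFR and FOXA1 stood at 0.0102, 0.039, 0.0285 and 0.12 under TFAP2A siRNA. In the response differences with the mean, PGR and GREB1 stood at 0.0348 and -0.19 without siRNA, -0.19 and 0.22 under TFAP2A siRNA, and 0.16 and -0.036 under TFAP2C siRNA, where PGR was also 0.0448 with medians subtracted and 0.0168 after quantile normalization.

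With an array left out, signs turned within these ranges. For estrogen they were -0.19 to 0.0313 for CCND1 and -0.0492 to 0.0772 for GATA3. Under TFAP2C siRNA they were -0.23 to 0.0106 for PGR, -0.21 to 0.42 for TFF1, -0.38 to 0.0444 for CCND1, -0.22 to 0.39 for EGFR, -0.0146 to 0.33 for CDKN1A and -1.20 to 0.43 for CXCL12. Under TFAP2A siRNA they were -0.11 to 0.41 for TFAP2C, -0.0323 to 0.43 for TFF1, -0.34 to 0.0928 for CCND1, -0.43 to 0.24 for FREM2, -0.15 to 0.38 for RERG, -0.27 to 0.0634 for EGFR, -0.10 to 1.42 for CXCL12, -0.036 to 0.0178 for FOXA1 and -0.045 to 0.16 for GATA3. Of 36 list calls, 31 held with the mean of probe sets, 30 with medians subtracted, 30 after quantile normalization and 6 with fry, which asks another question.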

Other observations

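All tests of explanations here were chosen after the result was seen, except the splits of the arrays counted with the trend fit.

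Interferon response genes rose under both siRNAs. Loss of TFAP2C alone is argued against by their median of 3.98 under TFAP2A siRNA, where TFAP2C differed by 0.15. Under the other scalings the lowest median over both siRNAs was 3.99, so the rise remained. Subtracting array medians moved the median difference of all genes under TFAP2A siRNA only from -0.07 to 0.06. These scalings could thus hardly have removed a rise of this size, whatever its source. A response to transfected RNA is a candidate explanation that cannot be told apart from an effect shared by both AP-2 siRNAs, since each state given a siRNA had one against an AP-2 gene. The difference between the siRNAs, 0.43 (0.22 with array medians subtracted), leaves both open.

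Replication and mitosis genes stood lower under TFAP2C siRNA. Transfection shared by both siRNAs, as the sole source, is argued against by their median of 0.30 under TFAP2A siRNA, with 58 of 64 members higher (0.43 with array medians subtracted, 0.29 after quantile normalization). A shared effect offset by an opposite effect of TFAP2A siRNA cannot be told apart, since no state had a siRNA without a target. A lost estrogen response is argued against by a median of -1.32 on the arrays without estrogen (-0.87 with it). Over the scalings the median nearest to 0 was -1.02, so the fall remained. Those scalings moved the median difference of all genes under TFAP2C siRNA only from -0.01 to -0.09 and -0.02. They could thus hardly have removed a fall of this size, whatever its source. That loss of TFAP2C lowers these genes is a hypothesis found and examined on the same arrays; an effect of this siRNA on other transcripts may give the same values.

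The p53 target genes stood lower under TFAP2A siRNA, and 16 of 22 were lower under both siRNAs. For the list, transfection shared by both siRNAs cannot be told apart from an effect of TFAP2A siRNA, since the difference between the siRNAs was 0.23 and 0.02 with array medians subtracted. For CDKN1A alone the difference was 1.42 (1.20 with array medians subtracted), which argues against the shared transfection as the whole source. Whether loss of TFAP2A lowers CDKN1A stays a hypothesis.

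The 6 arrays make 10 splits of 3 against 3, too few for a share under 0.05. For estrogen the default fit called 0 genes in the real split and at most 0 in the others, so all 10 gave as many and that count decides nothing. The trend fit called 236 in the real split and at most 0 in the others, so 1 of 10 gave as many. In 4 of the 10, the real one included, the arrays of each siRNA state lie on opposite sides. The others place both arrays of a siRNA state on the same side, against the model's siRNA term, so the comparable count is 1 of 4. Those of the 4 that are not the real split reverse 1 pair of arrays against the rest. A real estrogen effect then adds to the spread, so their 0 calls do not measure chance.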
